A study of Homo sapiens with 10 samples.

How the data were processed

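DRIP-seq was carried out on DLD1 cells grown with colcemid and either DMSO, AZD1152 (500 nM) or ZM447439 (2 uM), per the labels. Per the labels' protocols, hybrids were precipitated from sonicated chromatin with S9.6, libraries were made with a Takara SMARTer ThruPLEX kit, and sonicated yeast DNA was added at 10% before library preparation. Each sample's source name and growth protocol give DLD1, which was used here, but the treatment protocol field of every sample holds text that names HEK293, another human cell line, and this conflict could not be settled from the labels. The series design text names 2 sets of immunoprecipitations, each with an input, a control, an inhibited and RNase H1-treated samples. The labels do not say which set each inhibitor belongs to. Of the 10 samples, 2 DMSO, 1 AZD1152 and 1 ZM447439 sample had a peak list, and the 2 inputs and 4 samples treated with 40 U of RNase H1 were not analysed here. Nothing in the labels says whether the DMSO samples came from separate cultures, so their difference may be technical.

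BWA, SAMtools and MACS2 and the builds hg38 and sacCer3 are named in the submitters' processing notes, with no versions or roles, and per the series design text peaks were called against input. Each list was called on 1 sample. The fold of a peak is the ratio of the immunoprecipitated sample to its control at the summit, as the authors' peak caller wrote it to the deposited lists. The deposited lists also give a −log10 p-value and a −log10 q-value per peak, as the authors' caller wrote them. The lowest −log10 q was between 1.30 and 1.44 in the 4 lists. The score column of the deposited peak lists is 10 times the −log10 q, as the values show, and was not used. Starts, ends and summit positions are in bp on hg38 in the authors' files, and are printed here counted from 1. Whether and how the authors used the yeast reads to scale the samples is not given in the sources used here. The caller's settings for duplicate reads and for reads that map to several places are not given in the sources used here either, and both can change peaks in repeats.

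A pair of further files holds intervals that by their names are common to the DMSO samples and to the inhibitor samples. How the authors made these deposited intervals is not given in the sources used here. The score in the deposited common lists could not be interpreted. Score times width lay within 0.1% of its lowest size in 69.9% of intervals of the DMSO table and 48.6% of the inhibitor table in the authors' deposited table, so that it carries little beyond the width, and it was not used.

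The annotation was a table of 59792 RefSeq genes of assembly GRCh38.p14, the assembly of hg38. Only the 58998 genes placed on assembled chromosomes or the mitochondrial genome were used, since the table lists 794 scaffold genes under chromosome names. It gives no strand, no centromeres and no sequence. The planned results at transcription start and termination sites were therefore replaced by 1 result at both gene ends together, and the planned result in centromere models by 1 in gene-free intervals of at least 2 Mb. An interval of the short arm of Y, whose genes are listed on X, was left out. The planned sequence composition of peaks and a match of gene lists on GC content were not run, and placement did not avoid assembly gaps. Ratios to the placed share can therefore be too low in gene-free intervals. As a stand-in for gaps, chosen after seeing the data, placement was also kept out of 11 stretches of at least 1 Mb, 136 Mb of them in gene-free intervals, without a peak in any of the 4 lists or the 2 common lists.

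Peaks of 2 lists were called overlapping at 1 bp or more. Each peak was moved to a random position of its own chromosome, keeping its width, 1000 times (200 times for the common lists), and p is from this permutation of positions, the one-sided share of placements at least as extreme, with 0.001 the smallest possible. Merged regions join peaks of the 4 lists that overlap. A gene was counted as having a peak when a peak lay in its body or within 1 kb. For each of 26 gene lists fixed before the data were examined, members with a peak were compared with 10000 random gene lists matched in 20 length bins, with pseudogenes left out, and p-values were adjusted by the Benjamini-Hochberg method over 25 lists and 4 libraries. The mitochondrially encoded genes were counted without a test. Intervals are 95% Wilson intervals. Fragments at the summit were recovered as the whole number x for which fold = (x + 1) / (background + 1) and the Poisson tail above x match the fold and −log10 p of a peak within 0.002. With p-values shuffled among peaks, 20.4%, 2.91%, 5.12% and 3.94% of peaks matched by chance.

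Genes were named by a rule fixed before the data were examined. Up to 8 protein-coding genes with a peak in all 4 lists, up to 6 with a peak in both DMSO lists alone and up to 6 in both inhibitor lists alone were ranked by the lowest of their within-list percentiles of fold. Up to 3 members of each fixed gene list with a peak in the most lists, the peak of highest fold in each list and AURKB, INCENP, BIRC5 and CDCA8 completed the rule. Some genes that the rule takes are not reported here. Alternatives tried were a reciprocal overlap of 50%, a distance of 1 kb, a −log10 q of at least 5, a fold of at least 4, lists cut to an equal 1957 peaks by −log10 p, chromosomes 1 to 22 and X alone, other windows and gene sets, and leaving out each DMSO replicate.

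The steps were tested on simulated data. With 20% of the DMSO replicate 2 peaks planted on simulated DMSO replicate 1 peaks, 19.8% was recovered beyond placement, and with none planted 0.100%, in 20 runs each. For one simulated library and lists of 20 members, the gene list test passed an unadjusted 0.05 in 2 of 100 runs with no planted peaks and in 100 of 100 with 40% of members planted, over 42101 genes. Simulated members were drawn at random from all these genes, and their peaks depended on gene length alone. These runs therefore do not cover lists of very long, neighbouring or nested genes. Of 5000 simulated peaks of one list, 100% had their fragment number recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The total depth of the libraries is unknown. The recovered background, taken as its lowest value over the summits of a list, was 0.159, 0.413, 0.263 and 0.469 fragments in DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439.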

Results

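RNA-DNA hybrids were mapped in DLD1 cells, a human colorectal cancer line, that had been arrested in mitosis with colcemid, a microtubule poison. Hybrids were pulled down from sonicated chromatin with the S9.6 antibody, which binds RNA-DNA duplexes, and the DNA was sequenced (DRIP-seq). The series compared cells given DMSO, the solvent control, with cells given an inhibitor of Aurora B, the kinase of the chromosomal passenger complex, which sits at centromeres in mitosis. DMSO had 2 samples, AZD1152 at 500 nM had 1 and ZM447439 at 2 uM had 1. These 4 samples each had a peak list, and the 2 inputs and the 4 samples treated with RNase H1, an enzyme that degrades the RNA of hybrids, were not analysed here. The sensitivity of the peaks to RNase H1 was therefore not examined. With 1 sample per inhibitor there was no replicate error for either compound, and 2 lists against 2 lists cannot give a two-sided exact permutation p below 0.333. The p-values and the 95% Wilson intervals describe these libraries. The intervals cover counting error only, and peaks are not replicates of a condition.

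The 4 lists differed widely in length, the controls most of all. DMSO replicate 1 had 30880 peaks covering 7836.7 kb, and DMSO replicate 2 had 1957 peaks covering 836.7 kb. AZD1152 had 9200 peaks covering 3212.8 kb and ZM447439 had 5229 covering 1975.8 kb, so that both inhibitor lists lay between the 2 control lists. The number of sequenced fragments was not given in the files. The fold enrichment and p-value of each peak together fix the whole number of fragments stacked at its summit, and this number was recovered for 99.9%, 99.5%, 99.5% and 99.9% of peaks in the 4 lists, in the order just given. The median summit held 4 fragments in DMSO replicate 1, 7 in DMSO replicate 2, 5 in AZD1152 and 8 in ZM447439. In DMSO replicate 1, 93.8% of summits held 5 fragments or fewer, against 9.96%, 51.8% and 1.01% in the other lists. At a −log10 q of 5 or more, 1023, 368, 1106 and 876 peaks remained, and AZD1152 then had the longest list. On chromosomes 1 to 22 and X, 446 of its 971 peaks at that q lay in gene-free intervals of at least 2 Mb. The counts were 133 of 884 in DMSO replicate 1, 1 of 246 in DMSO replicate 2 and 14 of 729 in ZM447439. Outside these intervals AZD1152 did not have the longest list there.

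The peaks of highest fold lay on the mitochondrial genome in both DMSO lists, on chromosome Y in AZD1152 and on chromosome 2 in ZM447439. Peaks covered 94.3% of the mitochondrial genome in DMSO replicate 1, 100% in ZM447439, 92.8% in AZD1152 and nearly all of it, positions 5 to 16569, in DMSO replicate 2. All 15 mitochondrially encoded genes of the fixed list, among them ATP6, ATP8 and COX1, which encode subunits of ATP synthase and cytochrome c oxidase, had a peak in the body or within 1 kb in each list. The mitochondrial peak was the highest of its list in DMSO replicate 1 (17.0-fold over control, as the authors' peak caller gave it) and in DMSO replicate 2 (23.1-fold). The highest fold of the AZD1152 list, 14.6, was at chromosome Y, 56673253 to 56680997, where no gene is annotated. The highest of the ZM447439 list, 53.9, was at chromosome 2, 32916103 to 32916778, outside annotated genes and outside the peaks of the other 3 lists. Fold enrichment is used here only to describe and rank peaks within a list.

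Repeated blocks, picked after their values were seen, held peaks in every list. Between 56.67 and 56.78 Mb of chromosome Y, peaks covered 70.3% of the sequence in DMSO replicate 1, 34.0% in DMSO replicate 2, 84.5% in AZD1152 and 37.9% in ZM447439. In the ribosomal DNA block of chromosome 21, 8.2 to 8.47 Mb, the lists had 48, 34, 39 and 41 peaks. The transcribed units of that block differed: RNA45SN3, which encodes the 45S precursor of ribosomal RNA (chromosome 21, 8389035 to 8402343), had 3 peaks in DMSO replicate 1, 1 in DMSO replicate 2, 4 in AZD1152 and none in ZM447439. A stretch of chromosome 1 that holds pseudogenes of mitochondrial genes had peaks in all 4 lists, with a region at 629158 to 630208 over MTND1P23 and MTND2P28.

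The 2 control immunoprecipitations set the yardstick for the inhibitor lists. Genes with peaks in both DMSO lists and in neither inhibitor list numbered 84 among protein-coding genes, and included MMP16 (a matrix metalloproteinase), ADAMTS20 (a secreted metalloproteinase), SLC7A9 (an amino acid transporter), RGPD2, CCDC91 and COL19A1 (a collagen). MMP16, at chromosome 8, 88032011 to 88327483, had 5 peaks in DMSO replicate 1 and 1 in DMSO replicate 2. The median length of the 84 genes was 111 kb, against 24.4 kb for all protein-coding genes. Their number was not set against chance, and the peaks of both lists need not share a site within a gene. Of the DMSO replicate 2 peaks, 435 of 1957, 22.2% (20.4 to 24.1), overlapped a DMSO replicate 1 peak by at least 1 bp. Random placement of the same peaks on their own chromosomes gave 1.35% on average, so that the observed share was 16.5 times the placed share and above all 1000 placements (one-sided permutation of positions, p = 0.001, the smallest that 1000 placements can give). The share was 10.6% when at least 50% of both peaks had to overlap, and in lists of equal length it was 9.66%.

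**Figure D1:**
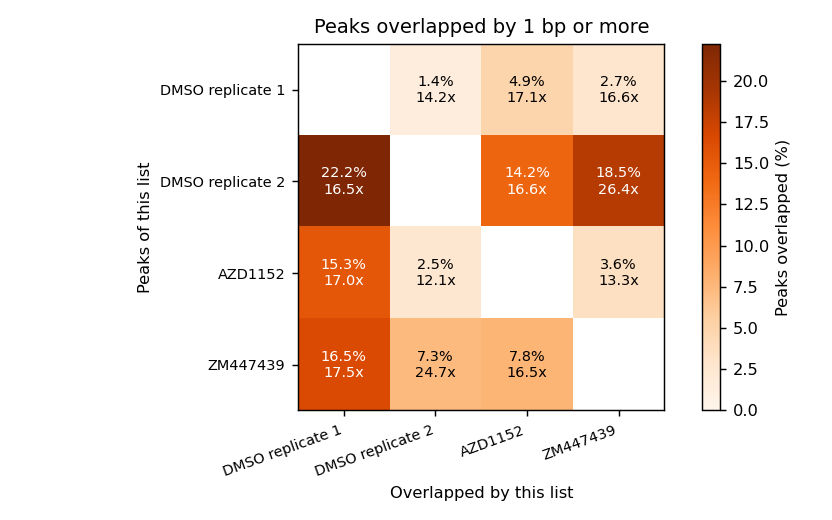
Share of the peaks of each list (rows) that overlapped a peak of another list (columns) by 1 bp or more, in percent, with its ratio to the mean of 1000 random placements below it. Each off-diagonal ratio lay between 12.1 and 26.4, and the highest share was the 22.2% of DMSO replicate 2 peaks overlapped by DMSO replicate 1.

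AZD1152 was compared with DMSO to ask where hybrids lie when Aurora B is inhibited. AZD1152 and DMSO replicate 1 alone had a peak in 1013 protein-coding genes, and AZD1152 and DMSO replicate 2 alone in 9. Neither count was set against chance, and the control lists differ in length. KNL1, a kinetochore scaffold (chromosome 15, 40594249 to 40664342), had 4 peaks in DMSO replicate 1, 1 in AZD1152, 1 in ZM447439 and none in DMSO replicate 2. ATR, a checkpoint kinase, and XRN2, a nuclease of transcription termination, each had 1 peak in DMSO replicate 1 and 1 in AZD1152. Of the AZD1152 peaks, 1491 of 9200, 16.2% (15.5 to 17.0), overlapped a peak of either DMSO list, 16.4 times the placed share of 0.990% and above all 1000 placements (permutation of positions, p = 0.001). The overlap came mostly from the longer control list: 15.3% of the AZD1152 peaks were overlapped by DMSO replicate 1 and 2.52% by DMSO replicate 2, 17.0 and 12.1 times their placed shares. In lists of equal length these shares were 16.7% and 5.52%, in the same order. The share overlapped by either DMSO list was 9.61% with a reciprocal overlap of 50% and 25.2% within 1 kb.

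ZM447439 peaks were set beside the same controls. Among genes of the fixed lists, MAD1L1, a spindle checkpoint protein, had 2 peaks in ZM447439 and 1 in DMSO replicate 1, and SGO2, a protector of centromeric cohesion, had 1 in each of these lists. CENPP, a centromere protein, had 1 peak in ZM447439 and 3 in DMSO replicate 1, and GRIN2B, a glutamate receptor subunit, had 1 and 1. Of the ZM447439 peaks, 1065 of 5229, 20.4% (19.3 to 21.5), overlapped a peak of either DMSO list, 18.4 times the placed share of 1.10% (permutation of positions, p = 0.001). DMSO replicate 1 overlapped 16.5% of them and DMSO replicate 2 overlapped 7.32%, which were 17.5 and 24.7 times the placed shares. In lists of equal length the order turned, with 9.81% overlapped by DMSO replicate 1 and 13.4% by DMSO replicate 2. The share overlapped by either DMSO list was 10.1% with a reciprocal overlap of 50% and 37.8% within 1 kb.

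The 2 inhibitors, given at different doses, were compared with each other. A set of 25 protein-coding genes had a peak in both inhibitor lists and in neither DMSO list. They included ACACB (an acetyl-CoA carboxylase), MRPS31 (a mitochondrial ribosomal protein), ACSS3 (an acyl-CoA synthetase), SLC30A7 (a zinc transporter), GTF2I (a transcription factor) and RASGEF1C. ACACB, at chromosome 12, 109111189 to 109268226, had 1 peak in each inhibitor list, MRPS31 had 1 in AZD1152 and 3 in ZM447439, and GTF2I had 2 and 1. The median length of the 25 genes was 103 kb, against 24.4 kb for all protein-coding genes. The number of genes was not set against chance, so it does not show a group set by treatment. Peaks of both lists need not share a site within a gene. Of the ZM447439 peaks, 406 of 5229, 7.76% (7.07 to 8.52), were overlapped by AZD1152, 16.5 times the placed share of 0.470% (permutation of positions, p = 0.001). This share lay below the 16.5% overlapped by DMSO replicate 1 and beside the 7.32% overlapped by DMSO replicate 2, lists that are longer and shorter than AZD1152. In lists of equal length AZD1152 overlapped 8.12%, below both DMSO lists. The share was 3.10% with a reciprocal overlap of 50% and 13.0% within 1 kb.

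Merging the 4 lists gave 43980 regions, of which 41425, 94.2%, were held by exactly 1 list. Both DMSO lists and neither inhibitor list held 183 regions, and both inhibitor lists and neither DMSO list held 127. The other pairs held 1142 for DMSO replicate 1 with AZD1152, 545 for DMSO replicate 1 with ZM447439, 165 for DMSO replicate 2 with ZM447439 and 57 for DMSO replicate 2 with AZD1152. With 3 ways to split 4 lists in pairs, the split by treatment could not be tested. In lists cut to an equal 1957 peaks, the DMSO pair held 49 regions and the inhibitor pair 18, against 227 for DMSO replicate 1 with AZD1152 and 135 for DMSO replicate 2 with ZM447439.

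**Figure D2:**
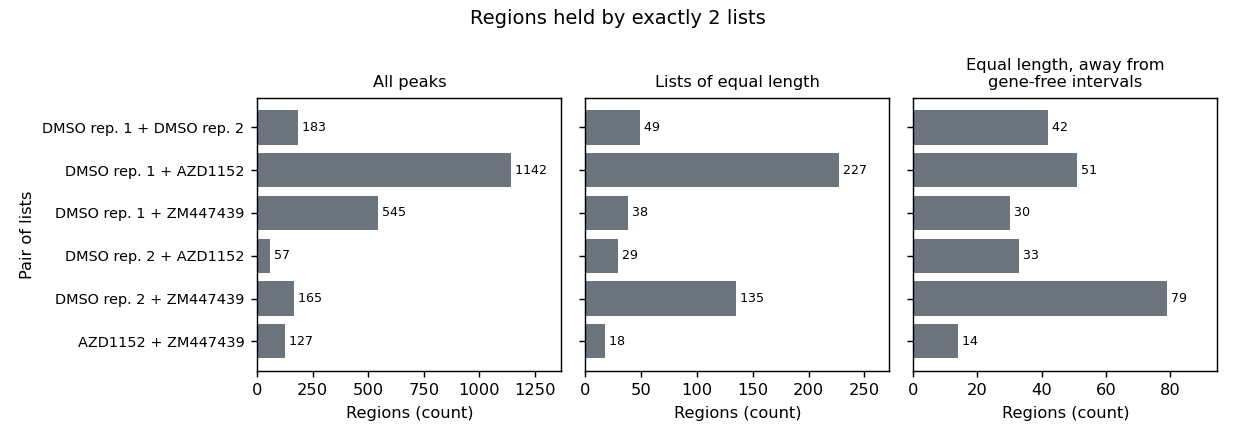
Number of merged regions held by exactly 2 of the 4 lists, for each pair (bars; horizontal axis, count), with all peaks, with the 1957 strongest peaks of each list, and with the 1434 strongest peaks of each list away from gene-free intervals and their 5 Mb flanks. The pair of DMSO replicate 1 and AZD1152 held 1142, 227 and 51 regions, and the inhibitor pair held 127, 18 and 14.

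All 4 lists held a peak at 82 regions and in 143 protein-coding genes. Long genes led this group, with a median length of 448 kb against 24.4 kb for all protein-coding genes. The genes ranked highest were TMEM117, NBAS (a factor of Golgi-to-ER transport), GALNT13 (a glycosyltransferase), BBX, RPS6KC1, HPSE2, STPG2 and EYS (a photoreceptor protein). TMEM117, at chromosome 12, 43795802 to 44399108, had 9, 2, 2 and 2 peaks in DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439. EYS, at chromosome 6, 63719980 to 65707226, had 28, 2, 4 and 8. None of these highest-ranked genes held any of the 82 regions, so their peaks in the 4 lists did not all meet at a common site. A longer gene catches more peaks by chance, and this count of genes was not matched on length. Of the 82 regions, 28 were on unplaced, unlocalized, alternate or fix sequences, 12 on chromosome Y, 16 on chromosome 21 near the ribosomal DNA and 1 was the mitochondrial genome. The other 25 included sites in OTOGL (chromosome 12, 80246885 to 80247616), GPC5, CYRIA, EHBP1, SUMF1, DOCK3 and SPTLC1, names read from these regions after their values were seen. Among genes of the chromosomal passenger complex, AURKB, INCENP and BIRC5 had no peak in any list, and CDCA8 had 1, in DMSO replicate 1.

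Peaks lay in gene bodies and at gene ends less often than random placement. They overlapped an annotated gene in 53.7% of cases in DMSO replicate 1, 44.8% in DMSO replicate 2, 43.3% in AZD1152 and 47.8% in ZM447439, where placement gave 56.0%, 54.3%, 55.8% and 55.3%. Within 1 kb of either end of a gene lay 4.15%, 4.09%, 3.69% and 2.89% of peaks, which were 0.606, 0.596, 0.513 and 0.423 times the placed shares. Each of these 8 shares was below all 1000 placements (one-sided permutation of positions, p = 0.001 each). Gene-free intervals of at least 2 Mb held 1810 of the 8928 AZD1152 peaks, against 1228 of 30322 in DMSO replicate 1. These intervals hold no gene, so part of the low AZD1152 share in genes follows from them. Start and termination sites were not separated, because the annotation used here carries no strand. Protein-coding genes with a peak in the body or within 1 kb numbered 5967, 469, 2245 and 1175, with median lengths of 83.4, 169, 115 and 176 kb. At a −log10 q of 5 or more, the depletion at gene ends was lost in ZM447439 (0.971 times the placed share) and its direction turned in DMSO replicate 2 (1.39 times, two-sided permutation p = 0.0959).

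**Figure D3:**
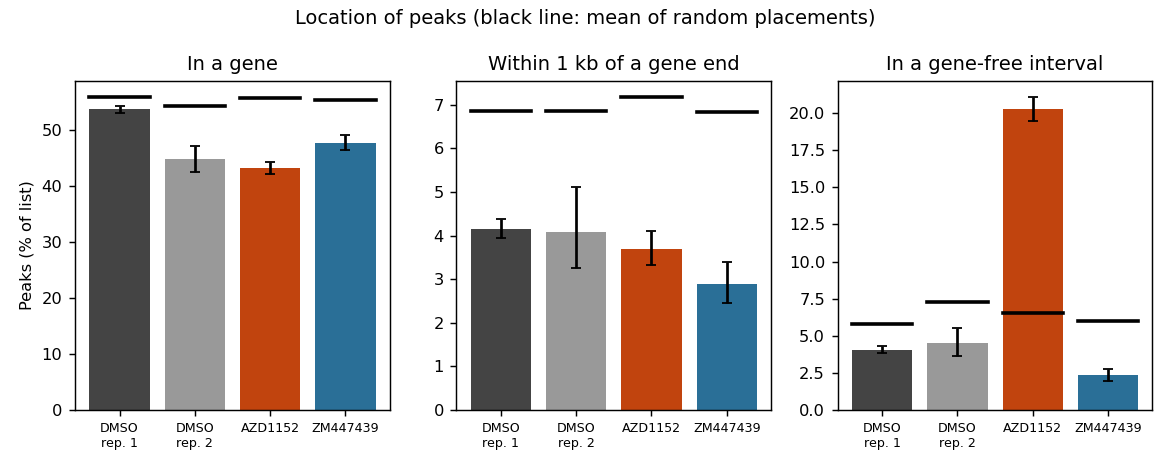
Share of peaks on chromosomes 1 to 22, X and Y that lay in a gene, within 1 kb of a gene end and in a gene-free interval of at least 2 Mb (bars, percent of the list), with 95% Wilson intervals as error bars and the mean of 1000 random placements (assembly gaps included) as black lines. AZD1152 placed 20.3% of its peaks in gene-free intervals, and the other lists between 2.31% and 4.48%.

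AZD1152 had the largest share of its peaks in gene-free intervals, and DMSO replicate 1 came next once chromosome Y was left out. These 28 intervals of at least 2 Mb without an annotated gene, 210.1 Mb in all, stood in for centromeres, whose positions were not used here. They were picked by lack of genes alone and are not all centromeric, since they include the start of chromosome 13 and a stretch of the long arm of Y. AZD1152 had 1810 of 8928 peaks in them, 20.3% (19.5 to 21.1), which was 3.11 times the placed share and above all 1000 placements (permutation of positions, p = 0.001). DMSO replicate 1 had 4.05% (3.83 to 4.28), DMSO replicate 2 had 4.48% (3.61 to 5.54) and ZM447439 had 2.31% (1.93 to 2.76), 0.703, 0.616 and 0.386 times the placed shares. These ratios below 1 are not a measure of depletion, because placement also used assembly gaps, where no peak can lie, and 64.6% of the length of the intervals lay in stretches of at least 1 Mb without a peak in any of the 4 lists or the 2 common lists. With placement kept out of these stretches, a check chosen after seeing the data that raises the ratios by construction, they were 1.63 in DMSO replicate 1, 1.94 in DMSO replicate 2, 7.59 in AZD1152 and 1.01 in ZM447439 (two-sided permutation of positions, p = 0.002 in the first 3, the smallest that 1000 placements can give, and 0.921 in ZM447439). Chromosome Y held most of these peaks in DMSO replicate 2 and ZM447439. On chromosomes 1 to 22 and X alone the shares were 3.87%, 1.22% (0.799 to 1.86), 20.1% and 0.891% (0.664 to 1.19) in DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439, which with placement kept out of the same stretches were 1.55, 0.515, 7.52 and 0.384 times the placed shares. In the interval of chromosome 9, 43139881 to 60832661, AZD1152 had 221 peaks, DMSO replicate 1 had 92, and DMSO replicate 2 and ZM447439 had none. Intervals of chromosome 18 (139 against 78), chromosome 20 (135 against 60) and chromosome 12 (112 against 71) also held more peaks in AZD1152 than in DMSO replicate 1, a list more than 3 times as long. AZD1152 had the most peaks of the 4 lists in 21 of the 27 intervals outside chromosome Y. DMSO replicate 1 had 10 or more peaks in 23 of the 27 and AZD1152 in 22, against 0 in DMSO replicate 2 and 0 in ZM447439. In the interval of chromosome Y the counts were 60, 59, 27 and 72. Counts there do not follow the length covered, because AZD1152 peaks were few and wide. Between 56.67 and 56.78 Mb, the 4 lists in the same order had 50, 56, 14 and 71 peaks. These covered 70.3%, 34.0%, 84.5% and 37.9% of the sequence. With 5 Mb on either side of all gene-free intervals added, the shares of peaks were 12.9%, 19.4%, 28.9% and 13.5%, which were 1.01, 1.35, 2.05 and 1.06 times the placed shares over the whole sequence, and 1.32, 1.93, 2.73 and 1.44 times with the stretches left out. In lists of equal length DMSO replicate 1 had 13.6% of its peaks inside gene-free intervals, AZD1152 had 34.4%, DMSO replicate 2 had 4.48% and ZM447439 had 4.46%. On chromosomes 1 to 22 and X alone these shares were 11.2%, 34.0%, 1.22% and 0.904%, so that DMSO replicate 1 lay between AZD1152 and the other lists. At a −log10 q of 5 or more, with placement over the whole sequence, the ratios were 2.19 in DMSO replicate 1, 1.201 in DMSO replicate 2, 5.46 in AZD1152 and 0.955 in ZM447439. Chromosome Y is included in these ratios. On chromosomes 1 to 22 and X alone at that q, the shares inside were 15.0%, 0.407%, 45.9% and 1.92% in the same order.

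**Figure D4:**
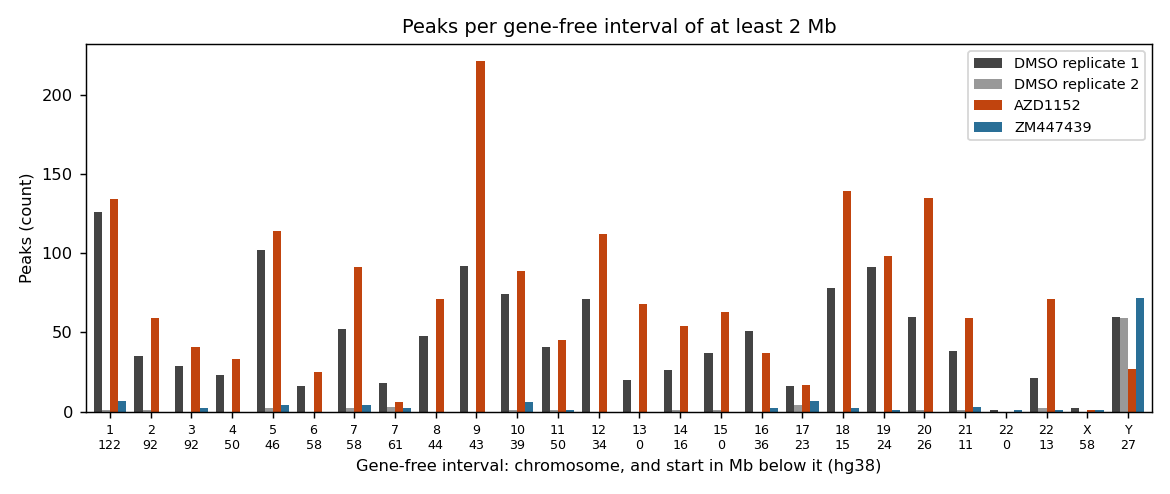
Number of peaks (vertical axis, count) in each gene-free interval of at least 2 Mb with more than 1 peak over the 4 lists, by chromosome and start in Mb, for the 4 lists. AZD1152 reached 221 peaks on chromosome 9, where DMSO replicate 1 had 92, and DMSO replicate 2 and ZM447439 had counts above 7 only on chromosome Y.

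Of the 26 gene lists fixed before the data were examined, 2 passed in 3 libraries each, ribosomal RNA genes and long genes of common fragile sites. They had more members with a peak than random lists matched in length bins, but the calls for fragile-site genes ended with closer matching on length. Ribosomal RNA genes with a peak numbered 9 of 29 in DMSO replicate 1, 4 in DMSO replicate 2, 9 in AZD1152 and 0 in ZM447439, with 0.913, 0.0757, 0.222 and 0.0761 in random lists (permutation of list membership, adjusted p = 0.0025 in each of the first 3 lists, Benjamini-Hochberg over 100 tests). These were genes of the 45S repeat, such as RNA28SN3, RNA45SN3 and RNA18SN2 on chromosome 21, and none of the 17 5S genes had a peak. The copies of the repeat are near-identical. Members are also nested, as RNA28SN3 lies inside RNA45SN3, so that 1 peak can count for more than 1 member and they are not independent. Long genes of fragile sites, such as LSAMP, CTNNA3 and DLG2, had a peak in 19 of 19 members in DMSO replicate 1 (permutation, adjusted p = 0.544), 10 in DMSO replicate 2 (0.004), 18 in AZD1152 (0.0025) and 15 in ZM447439 (0.005). All 3 calls ended when each gene was matched to its 200 nearest genes by length, which gave 6.71, 15.0 and 12.6 members in random lists (permutation, adjusted p = 0.693, 0.554 and 0.970), a check chosen after seeing the data. Olfactory receptor genes, among them OR3A2, OR4N2 and OR2L13 with a peak in all 4 lists, had 15 of 387 members with a peak in AZD1152 against 6.82 (permutation, adjusted p = 0.0329), and 29, 5 and 5 in DMSO replicate 1, DMSO replicate 2 and ZM447439 (0.794, 0.0625 and 0.544). With the matching to nearest genes the ratio to random lists hardly moved, from 2.20 to 2.21, and the permutation p went from 0.0023 to 0.0031 unadjusted and to 0.0775 adjusted, above the threshold of 0.05, which ended the call. Both ways of matching used gene length alone, and took no account of regional peak density or of members that lie near each other. In 0 of the 100 tests did a list hold fewer members with a peak than random lists at an adjusted p under 0.05.

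Other lists did not pass the test. Colon epithelial genes, such as TSPAN8, AXIN2 and CDH1, had a peak in 9 of 23 members in DMSO replicate 1 against 4.38 in random lists (permutation, adjusted p = 0.0964), and in 0, 1 and 1 in the other lists. Genes of the centromere and kinetochore, such as CENPE, had 13, 0, 3 and 2 of 28 members with a peak, cohesin and condensin genes, among them PDS5B, STAG1 and WAPL, had 11, 3, 3 and 1 of 19, and mitotic kinase and passenger complex genes had 5, 0, 0 and 2 of 23. Factors that resolve or suppress hybrids had 12, 0, 4 and 0 of 25, numbered zinc finger genes, such as ZNF215, had 150, 6, 46 and 21 of 509, and snoRNA genes, such as SNORD44, had 18, 0, 3 and 0 of 568. Transfer RNA genes, such as TRG-CCC1-1, had 6, 0, 2 and 0 of 421, and cytoplasmic ribosomal protein genes, such as RPL31, RPS27A and RPL27A, had 4, 0, 3 and 0 of 83. Loci often used as positive controls in such work had a peak in DMSO replicate 1 alone, in 2 of 7 members, among them RPL13A. Of 3 loci used as negative controls, SNRPN had 4 peaks in DMSO replicate 1 and 1 in AZD1152. A peak anywhere in this gene of 155 kb or within 1 kb of it counted. Random lists gave 0.865 and 0.298 of 3 members with a peak in these libraries, against 1 in each. Histone genes had 1 of 69 members with a peak (H2AC4, in DMSO replicate 1), and small nuclear RNA genes (44) and immediate early genes (18) had none in any list. SR splicing factors, such as SRSF4, had 3, 0, 1 and 0 of 12, interferon-stimulated genes, such as MX2, had 3, 0, 1 and 0 of 21, glycolysis genes, such as PFKP, had 2, 0, 0 and 0 of 17, and telomere and nuclear long noncoding RNA genes, such as KCNQ1OT1, had 1, 0, 1 and 1 of 11. Among genes of other tissues, liver genes such as TF had 2, 0, 1 and 1 of 15 members with a peak, against 2.16, 0.115, 0.668 and 0.292 in random lists, neuronal genes such as STMN2 had 4, 0, 0 and 2 of 15, against 6.72, 0.790, 2.87 and 1.92, blood cell genes had 1, 0, 0 and 0 of 15, and fibroblast and muscle genes had 1, 0, 0 and 0 of 13 (TTN).

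Chromosome 2 from 30 to 70 Mb carried more peaks per Mb than other autosomes, and chromosome X fewer, in each of the 4 lists, a block picked after its values were seen. The block of chromosome 2 had 2.40, 3.22, 3.12 and 3.52 times the density of the other autosomes in DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439, and chromosome X had 0.320, 0.233, 0.204 and 0.341 times that density. The rest of chromosome 2 had between 0.894 and 1.12 times. This block was not the only raised stretch. On chromosome 11, the bins of 5 Mb starting at 0 and 5 Mb held 90 and 141 peaks in DMSO replicate 1 and 6 and 9 in DMSO replicate 2. They held 31 and 56 in AZD1152 and 16 and 24 in ZM447439. Autosomes other than chromosome 2 averaged 10.4, 0.597, 2.53 and 1.71 peaks per Mb outside gene-free intervals, in the same order of lists.

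**Figure D5:**
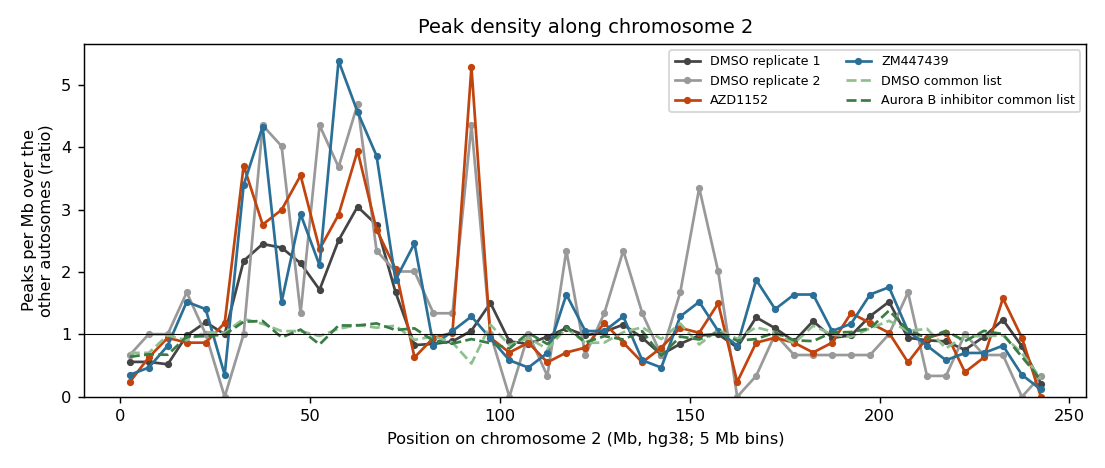
Peaks per Mb in 5 Mb bins along chromosome 2, divided by the mean density of the other autosomes outside gene-free intervals (vertical axis, ratio), for the 4 lists (solid lines) and the 2 common lists the authors deposited (dashed lines). From 30 to 70 Mb the 4 lists averaged 2.40 to 3.52, and the common lists 1.11 and 1.09.

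The common list for DMSO in the authors' deposited table had 96631 intervals over 32173 kb, more than both DMSO lists together. The authors' deposited table for the Aurora B inhibitors had 90272 intervals over 28001.7 kb. In the authors' deposited table, 19.6% of the DMSO intervals overlapped an inhibitor interval, 10.7 times the placed share, and 18979 of the 90272 inhibitor intervals overlapped a DMSO interval. The regions held by both DMSO lists were found in the authors' deposited table for DMSO in 216 of 392 cases, 55.1%, and those held by both inhibitor lists in the table for the inhibitors in 180 of 336, 53.6%. Of the DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439 peaks, 21.8%, 17.1%, 12.5% and 21.5% overlapped the authors' deposited table for DMSO, and 11.5%, 21.1%, 14.4% and 31.5% overlapped the authors' deposited table for the inhibitors. DMSO replicate 2 thus overlapped the inhibitor intervals of the authors' deposited table more often than the DMSO intervals. Gene-free intervals held 1.54% of the DMSO intervals and 2.67% of the inhibitor intervals of the authors' deposited table.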

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

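Of the tests in this part, those on an effect of both inhibitors, on gene density, on list length as a cause of the pairing and on gene-free intervals as its cause were chosen after their results or related values had been seen, and the patterns themselves had been seen before any test was set. AZD1152 lay above both DMSO lists and ZM447439 below both in the share of peaks in gene-free intervals, with 20.3% and 2.31% against 4.05% and 4.48%, and in the share in the longest gene-free interval of each chromosome, with 18.1% and 2.19% against 3.71% and 4.09%. The share of peaks on chromosome X went the other way, with 0.859% in AZD1152 and 1.70% in ZM447439 against 1.63% and 1.07% in the DMSO lists. The difference of ZM447439 from DMSO replicate 2 rests on chromosome Y and on list length: on chromosomes 1 to 22 and X it had 0.891% (0.664 to 1.19) and DMSO replicate 2 had 1.22% (0.799 to 1.86), and in lists of equal length 4.46% and 4.48%. Its difference from DMSO replicate 1 remained, with 3.87% and 13.6% in that list. Each inhibitor had 1 sample, and the differences between the inhibitors were not tested.

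The excess of AZD1152 peaks in gene-free intervals, such as those of chromosomes 9, 18 and 20, was weighed first. Weak peaks diluting the other lists are argued against as the whole cause: in lists of equal length AZD1152 had 34.4% (32.2 to 36.6) of its peaks inside and the next list, DMSO replicate 1, had 13.6%. With all peaks these shares were 20.3% and 4.05%, so dilution stays open as a part of the difference from DMSO replicate 1. An effect shared by both Aurora B inhibitors stays open, because ZM447439 lay below both DMSO lists with all peaks (2.31%, 1.93 to 2.76), but at a −log10 q of 5 on chromosomes 1 to 22 and X its 1.92% (1.15 to 3.20) lay between the 0.407% of DMSO replicate 2 and the 15.0% of DMSO replicate 1. Reads collapsed from repeats that the assembly compresses are a candidate explanation, since the recovered input background of AZD1152 peaks inside was 2.66 times that of its peaks elsewhere; without chromosome Y it was 0.785 fragments inside and 0.295 elsewhere in AZD1152, 0.312 and 0.159 in DMSO replicate 1, 0.558 and 0.481 in DMSO replicate 2 (21 peaks inside) and 0.772 and 0.579 in ZM447439 (43 peaks inside). An effect of AZD1152 itself, at 500 nM, and a difference between the sets of immunoprecipitations stay open and untested.

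In lists of equal length, DMSO replicate 1 with AZD1152 and DMSO replicate 2 with ZM447439 held more regions alone (227 and 135) than the DMSO pair (49) or the inhibitor pair (18), but with all peaks DMSO replicate 2 with ZM447439 held 165 and the DMSO pair 183. At equal length the lower of these counts, 135, lay above the highest of the other pairs, 49, by more than counting error. The pairing was itself read from these lists of equal length, so this is no separate test of list length as its cause. Gene-free intervals and their flanks stay open as a cause for DMSO replicate 1 with AZD1152, because away from them these counts were 51, 79, 42 and 14, and 51 and 42 differ by less than counting error. Regional peak density, such as copy number, also stays open, since the excess over placement within 500 kb was 1.04 (0.770 to 1.42) times that of the highest other pair. A shared set of immunoprecipitations could give this pairing, but the labels do not place the inhibitors in sets, and it was not tested. The recovered background ran in the same pairs, at 0.159 and 0.263 fragments in DMSO replicate 1 and AZD1152 against 0.413 and 0.469 in DMSO replicate 2 and ZM447439. So did the narrowest peak, at 152 and 219 bp against 263 and 292 bp. Lists of equal length do not make the libraries alike in these, and their part in the pairing was not tested.

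Peak density was raised at chromosome 2, 30 to 70 Mb, and lowered on chromosome X. Copy number of the cell line stays open as a cause: in 8 of 8 comparisons over the 4 lists, the share of peaks on an input background above the genome-wide level was larger in the block and smaller on X than on other autosomes (in DMSO replicate 1, 53.1%, 21.5% and 32.1%), but on X the interval held the autosome share in DMSO replicate 2 (57.1%, 36.5 to 75.5, against 70.4%) and AZD1152 (47.4%, 36.7 to 58.4, against 57.8%). In the authors' deposited table the common lists for DMSO and for the inhibitors had 1.11 and 1.09 times the density of other autosomes in the block and 0.820 and 0.801 times on X. The gene density of the block is argued against as the whole cause, since peaks outside genes were raised too, at 2.33 (2.11 to 2.58) times the density outside genes of other autosomes in DMSO replicate 1, the lowest of the 4 lists. No biological explanation was tested, and copy number itself was not measured here.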

How the results depend on the processing

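The alternatives with placement within 500 kb, the longest gene-free interval, chromosomes 1 to 22 and X for gene-free intervals, placement outside stretches without a peak, and the 200 nearest genes by length were chosen after seeing the data. Of 179 alternatives, 129 kept the direction and the side of the threshold, or a count within 1.5 times, among them all for overlap shares, gene bodies and the authors' deposited table. Some of the 129 could not have come out otherwise. Merging overlapping peaks left each list as it was, since no peaks within a list overlapped. Lists of equal length hold DMSO replicate 2 whole, so its ratios for genes, gene ends and gene-free intervals could not move. The share of DMSO replicate 2 peaks overlapped by DMSO replicate 1 ranged from 9.66% to 34.3%. The AZD1152 share overlapped by DMSO ranged from 1.64% to 25.2% (2.52% without DMSO replicate 1, 15.3% without DMSO replicate 2), the ZM447439 share from 3.42% to 37.8% (7.32% and 16.5%), and the ZM447439 share overlapped by AZD1152 from 3.10% to 14.8%. The cause of the changes below was not tested, except that stricter or shorter lists hold fewer peaks and that placement over the whole sequence puts peaks in assembly gaps.

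At a −log10 q of 5 or more, the lists held 1023, 368, 1106 and 876 peaks, and at a fold of 4 or more DMSO replicate 1 held 15744. Regions in both DMSO lists alone fell from 183 to 9 at that q and 49 in lists of equal length, and regions in both inhibitor lists alone from 127 to 8 and 18. Leaving out a DMSO replicate gave 1452 (without DMSO replicate 1) and 28739 (without DMSO replicate 2) DMSO regions, and 238 and 143 inhibitor regions. Ratios to the placed share at that q were 1.39 for DMSO replicate 2 (reversed) and 0.971 for ZM447439 at gene ends, and 2.19 for DMSO replicate 1 and 1.201 for DMSO replicate 2 (both reversed) and 0.955 for ZM447439 in gene-free intervals. Without chromosome Y, 1 of 246 DMSO replicate 2 peaks at that q, 0.407%, lay in gene-free intervals, so that its reversal there rests on Y. In lists of equal length DMSO replicate 1 had 1.73 in gene-free intervals (reversed). With 5 Mb added, DMSO replicate 1 had 2.10 at that q, 1.725 in lists of equal length and 0.935 with 2 Mb in place of 5 (reversed), and ZM447439 had 1.47, 1.21 and 0.916 (reversed). With placement outside stretches without a peak, the ratios in gene-free intervals were 1.63 for DMSO replicate 1, 1.94 for DMSO replicate 2 and 1.01 for ZM447439 (all reversed), and on chromosomes 1 to 22 and X 1.55 for DMSO replicate 1 (reversed), 0.515 for DMSO replicate 2 and 0.384 for ZM447439. With 5 Mb added they were 1.32 for DMSO replicate 1 and 1.44 for ZM447439, both now past the threshold.

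Gene list calls numbered 7, and 2 with gene ends alone, 4 in lists of equal length, 2 among genes with a peak in any list and 3 with the 200 nearest genes by length. In the same order, members over random lists were 0.947 (reversed), 1.81, 1.72 and 2.21 for olfactory receptors in AZD1152, 0 (reversed), 1.34, 1.38 and 1.2001 for fragile-site genes in AZD1152, and 0 (reversed), 2.59, 1.299 and 1.19 for fragile-site genes in ZM447439. Fragile-site genes in DMSO replicate 2 had 2.13 among genes with a peak and 1.49 with nearest genes, and no value with gene ends. Ribosomal RNA genes had 1.29 among genes with a peak in DMSO replicate 1 and 31.9 with gene ends in DMSO replicate 2, neither past the threshold. Named genes were rerun where they were named by their pattern over the 4 lists or always reported, and not where named from a fixed gene list. Of the 21 such genes with a peak in any list, 3 kept their number of lists at a −log10 q of 5 and 9 in lists of equal length, and 5 and 2 had no list left.

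No paired analysis was possible because the inhibitor samples carry no replicate number and each is a single sample. Separate start and termination sites, centromere models, sequence composition, GC-matched lists and placement outside annotated assembly gaps were not run. In DMSO replicate 1, 93.8% of summits held 5 fragments or fewer, which limits the precision of its weak peaks.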

Other observations

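The regions and blocks here were picked after their values were seen, and none was tested. A block of chromosome 8 with a cluster of REXO1L pseudogenes, 85.64 to 85.78 Mb, held 9, 10, 8 and 11 peaks in DMSO replicate 1, DMSO replicate 2, AZD1152 and ZM447439, and 4 of the 82 regions found in all 4 lists, which lie within it, begin at 85653262, 85742708, 85760382 and 85773614. Further regions found in all 4 lists lay in LINC01811 on chromosome 3 (34417580 to 34418108), LINC02108 and LINC01470 on chromosome 5 and FAM157C on chromosome 16 (90116746 to 90117360). Peaks covered 5.85% of the block of mitochondrial pseudogenes on chromosome 1 in AZD1152 and 65.3% in ZM447439, against 10.0% and 33.2% in DMSO replicate 1 and DMSO replicate 2. KCNQ1OT1, a nuclear long noncoding RNA gene, had 2 peaks in DMSO replicate 1, 2 in AZD1152 and 2 in ZM447439, and none in DMSO replicate 2.

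Across 492 bins of 5 Mb away from gene-free intervals, peak counts correlated between lists with a Spearman rho of 0.563 for DMSO replicate 1 and AZD1152, 0.489 for DMSO replicate 2 and ZM447439, 0.401 for DMSO replicate 1 and ZM447439, 0.270 for the 2 inhibitors, 0.254 for DMSO replicate 2 and AZD1152 and 0.240 for the DMSO lists. Bins are not independent replicates, and no p-value is given.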
